A study of Mus musculus with 10 samples.

How the data were processed

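The series held 10 single-channel oligonucleotide arrays of mouse embryonic ovary, 2 per stage at E11.5, E12.5, E14.5, E16.5 and E18.5, and every array was mapped to its stage and replicate from its title. Per the labels, RNA was extracted with Trizol and biotin-labelled by the single cycle protocol of the array maker, and the preparations of a stage were independent. The deposited value table held intensity values on a linear scale, 1 signal per probe set with no detection call. The deposited signals had been scaled by the authors, since the mean left after trimming 2% at each end was 125 on every array, and they had not been quantile normalized, since the array medians differed. The software that made the signals was not given in the sources used here. The deposited experiment files held other content, namely wash and scan settings with no expression values, and were used for the array type and for the 3 wash runs and the wash module of each array.

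The table had 45101 probe sets, of which 64 control probe sets were left out of the tests. Gene symbols came from the probe annotation of the series: 34945 probe sets had 1 symbol, 932 several and 9160 none, and 34754 of those with 1 symbol were matched by gene identifier to a current gene table, which updated 0 symbols. Array medians ran from 36.7 to 91.0, a ratio of 2.48, over the limit of 1.5 set for it, so each array was scaled to a common 75th percentile of 142. Without E12.5 replicate 2 the ratio was 1.43, under the limit, and the 9-array fit kept the scaling. Of the probe sets called for E18.5 against E11.5 with 9 arrays 44.8% were higher, and 56.7% on values as deposited, so which direction held the majority depended on the scaling. Of 394 named-gene results of the 9-array fit 355 stayed the same on values as deposited, 39 were weaker and 0 reversed. Values were then taken as log2 of the scaled signal plus 16. A probe set was tested when at least 2 arrays lay at or above the median of all values, which left 28857 with 10 arrays and 27510 with 9. For gene counts, gene lists and named genes the probe set with the highest mean stood for its gene, 13769 genes with 10 arrays and 13305 with 9.

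Tests were run with limma 3.58.1 in R 4.3.3 (lmFit with 1 mean per stage, eBayes with an intensity trend), with an F test over the 5 stages and contrasts of neighbouring stages and of E18.5 with E11.5. Adjusted p-values are Benjamini-Hochberg over all probe sets tested, with 0.05 as the threshold, and a two-sided test throughout. The gene lists were tested with camera of limma at a preset correlation of 0.01 and, as an alternative, at an estimated one, with adjustment over the lists of a contrast. Tables and figures were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9. With 10 arrays the residual degrees of freedom were 5 and the prior ones 4.33, and with 9 arrays 4 and 9.26.

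The scaling rule, the filter, the 10-array fit, the contrasts, the gene lists, the rule for named genes and the alternatives of the 10-array fit other than array weights were set in advance. The 9-array fit with its alternatives, the fit without both E12.5 arrays, array weights and the comparison of E14.5 with E11.5 were chosen after the data were seen. Genes were named by size of change: the largest increases and decreases per contrast among genes past the test whose arrays did not overlap, the members of each list with the largest change past the test, and the genes with the largest gap of one stage mean over the next. Other genes are said to be named after their values were seen, or come from the marker lists below.

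The lists covered germ cells (pluripotency and primordial germ cell, general germ cell, meiotic prophase, oocyte and primordial follicle), gonadal and neighbouring tissue (pregranulosa and ovarian somatic, early gonad and coelomic epithelium, testis somatic, steroidogenesis, mesonephros and ducts), other cell types (erythroid, macrophage and leukocyte, endothelial, stroma and extracellular matrix, smooth muscle, skeletal muscle, neural crest and neuron) and processes from the cell cycle to signalling and metabolism. Marker lists of hepatocytes and of the exocrine pancreas were written after some of their genes had been seen among the largest changes.

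The procedure was tested on simulated data with the arrays of the comparison of E18.5 with E11.5, with 27510 probe sets of which 200 were changed, in 5 simulations. With 9 arrays 11.4% of the probe sets changed by a factor of 2 and 79.6% of those changed by a factor of 4 were recovered, and 2.78% of the calls were false. With 10 arrays of one quality the shares were 24.0%, 82.6% and 4.48%, and with E12.5 replicate 2 as far off as in the data 0 were recovered. Far fewer probe sets were changed than were called in the data, and the offsets of E12.5 replicate 2 were shuffled over probe sets. The shares are thus not the power of the real comparison, where the 10-array fit called 302.

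Alternatives tried were another pseudocount (1 or 64), no filter or a stricter one, quantile normalization, values as deposited, the replicate number as a block, eBayes without a trend, a further threshold of a 2-fold change, fits of the stages of a contrast alone, the mean of all probe sets of a gene, and leaving out each array in turn. The wash runs could not be fitted as a block, since each stage lay in 1 run.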

Results

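Transcripts of the embryonic mouse ovary were measured on oligonucleotide arrays at 5 stages, E11.5, E12.5, E14.5, E16.5 and E18.5, with 2 arrays per stage and 10 arrays in all. The labels call the preparations of a stage independent duplicates. These days span the mitotic germ cell, the entry of female germ cells into meiosis and the first oocyte genes before follicles form, and the comparisons ask which transcripts changed between neighbouring stages and over the whole span. Each array gave signals for 45101 probe sets, 45037 of them other than control probe sets. Signals are given as scaled signal, mean ± SD over the 2 arrays of a stage, and changes on the log2 scale ± SE. The small number of arrays limits the precision of every value.

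The E12.5 arrays stood apart from the rest. The log2 signals of E12.5 replicate 2 correlated with those of any other array at r between 0.418 and 0.470 across probe sets, which are not independent replicates, against 0.873 to 0.964 among the other 9 arrays. Its spiked control probe sets had a median deposited signal of 23134, against 770 to 2380 on the other arrays, and its 3′ Gapdh control read 800 against 2894 to 6555. On E12.5 replicate 1 the 3′ to 5′ signal ratio of the Actb control was 10.6, against 1.51 to 2.22 on the 8 arrays of the other stages, and that of Gapdh was 2.17 against 0.755 to 1.28. On E12.5 replicate 2 these ratios were 4.09 for Actb and 2.39 for Gapdh, also above those 8 arrays. The arrays were washed in 3 runs, E11.5 with E12.5, E14.5 with E16.5, and E18.5 alone, so run and stage cannot be told apart between runs.

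**Figure D1:**
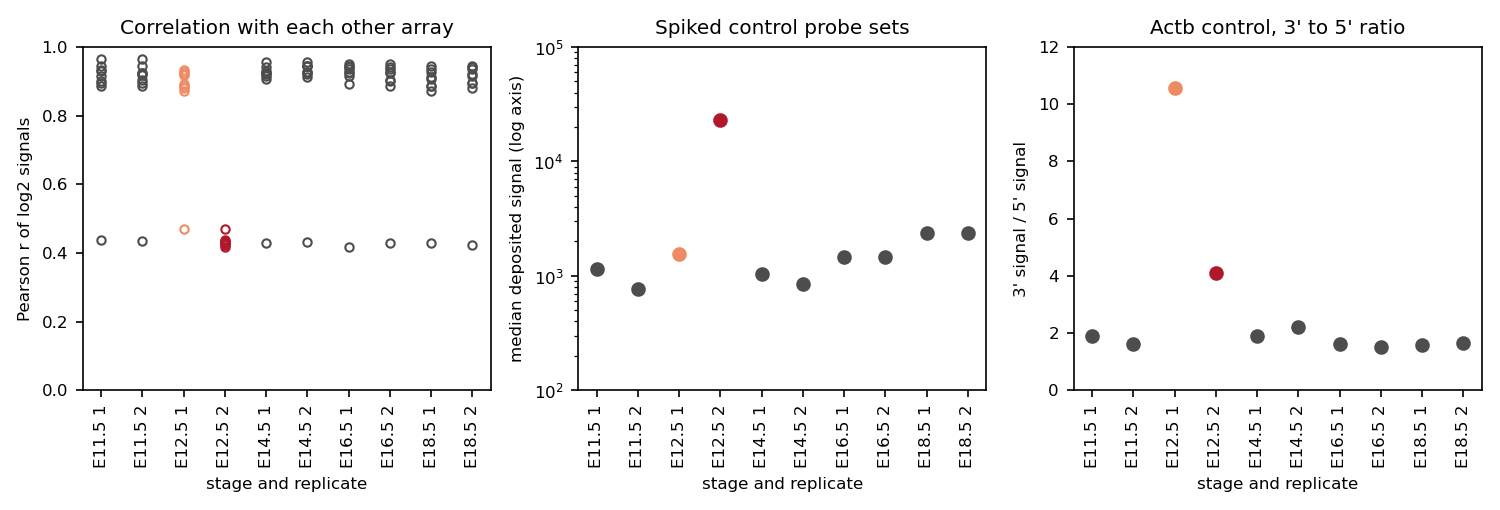
Each point is 1 array (correlation with each other array, left; median deposited signal of the spiked control probe sets on a log axis, middle; 3′ to 5′ ratio of the Actb control, right), with E12.5 replicate 1 in orange and E12.5 replicate 2 in red. E12.5 replicate 2 has no correlation above 0.470 and a spiked control median of 23134, and E12.5 replicate 1 has the highest Actb ratio, 10.6.

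All comparisons come from limma with 1 mean per stage. The fit of all 10 arrays was chosen before the data were examined. A fit of the 9 arrays without E12.5 replicate 2 was chosen after the data were seen, and in it E12.5 is a single array that is assumed to vary like the other stages. On that single array, E12.5 replicate 1, the 2 brightest probe sets of a gene disagreed more. The difference of their deviations from neighbouring stages had an SD of 0.839, against 0.438 to 0.534 on the E14.5 and E16.5 arrays. The assumption may thus fail, and SEs and adjusted p-values of 9-array comparisons with E12.5 may be too small. For comparisons that leave E12.5 out, the 2 fits give a probe set the same change with different errors, and the median SE over probe sets was 0.503 with 10 arrays and 0.275 with 9. Genes ranked by the size of their change had both arrays of one stage above both arrays of the other, with E12.5 a single array in the 9-array fit. Control probe sets with no spiked target had a 95th percentile of 18.7 to 33.5 on the 9 arrays other than E12.5 replicate 2, and of 203 on that array. The size of a change from or to signals in or under these values depends on the 16 added before the logarithm and is not exact. This holds for E12.5 means of the 10-array fit wherever E12.5 replicate 2 read under 203.

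Over the whole span, from E11.5 to E18.5, Bzw2, given below, had the largest increase of any named gene with 16 added before the logarithm. Genes of meiosis and of the oocyte were among the next 11, and this order depends on the value added. Sycp1, Sycp3 and Syce3, parts of the synaptonemal complex that joins homologous chromosomes, rose by 6.18 ± 0.77, 5.58 ± 0.65 and 5.55 ± 0.40 in the 10-array fit, with adjusted p of 0.00698, 0.00471 and 9.09e-04. The scaled signal of Sycp3 went from 44.4 ± 16.8 to 2822 ± 254 (SD, n = 2 each). Lhx8 and Figla, transcription factors of the early oocyte, rose by 6.13 ± 0.64 and 4.95 ± 0.35, from 2.30 ± 1.30 and 23.5 ± 8.95 to 1268 ± 59.6 and 1187 ± 70.1. At E11.5 both arrays of Lhx8 and 1 of Figla lay under the 95th percentile of the unspiked controls, and the change of Lhx8 was 8.65 with 1 added and 4.33 with 64. Smc1b, a cohesin subunit of meiotic chromosomes, rose by 5.18 ± 0.59. Terb1, which ties telomeres to the nuclear envelope, rose by 4.76 ± 0.47, and Mael, which acts in transposon silencing, by 5.22 ± 0.42.

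By group, 15 of 39 measured genes of meiotic prophase rose and 0 fell in the 10-array fit, and 32 rose and 0 fell with 9 arrays. Adjusted over the list alone, the 10-array counts were 29 higher and 0 lower. Of the oocyte and primordial follicle genes, 7 of 24 rose and 0 fell with 10 arrays, and 14 of 23 rose and 0 fell with 9. Besides Lhx8 and Figla these included Nlrp5, a maternal effect gene, which rose by 4.75 ± 0.32, and Nlrp4f, by 4.32 ± 0.66, in the 10-array fit. Of 20 general germ cell genes 9 rose and 0 fell with 10 arrays, and 19 rose and 1 fell with 9, among them Tex101 (4.69 ± 0.33), Mov10l1 (4.08 ± 0.41) and Stk31 (3.98 ± 0.44). Tested against all other genes with camera, the 3 lists were higher at E18.5 with adjusted p of 1.41e-27, 3.29e-15 and 5.71e-22 in that order in the 10-array fit. They also passed with adjusted p = 0.00448, 0.00448 and 0.00588 with an estimated correlation, and in the 9-array fit with adjusted p = 0.0435, 0.0253 and 0.01996 with an estimated correlation.

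Hba-x and Hbb-bh1, globins of primitive red blood cells, had the largest decreases and fell by 6.84 ± 1.12 and 6.71 ± 1.10 in the 10-array fit (adjusted p = 0.0239 and 0.0243), from 5817 ± 1123 and 6665 ± 2457 to 34.3 ± 2.37 and 46.1 ± 10.3. Sox2, a transcription factor of pluripotent cells, fell by 3.98 ± 0.51, from 366 ± 45.2 to 9.84 ± 13.2. Robo1, Aplnr, Klhl4 and Shisa3 changed by -3.47 ± 0.36, -3.49 ± 0.56, -4.23 ± 0.73 and -4.04 ± 0.50. With 9 arrays Pou5f1 and Nanog, which maintain pluripotency, also fell, by 2.56 ± 0.48 and 2.42 ± 0.38, and Hmga2, a chromatin protein of growing embryonic tissue, fell by 3.91 ± 0.20.

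Of 20 genes of pluripotency and primordial germ cells 1 fell and 0 rose with 10 arrays, and 13 fell and 3 rose with 9. Of 29 mitotic cell cycle genes 25 fell and 1 rose with 9 arrays, among them Cdc20 (-2.60 ± 0.31) and Top2a (-1.98 ± 0.20), while 0 passed in either direction with 10. Of 30 DNA replication genes 16 fell and 0 rose with 9 arrays, including the helicase subunit Mcm7 (-2.75 ± 0.22) and the ribonucleotide reductase subunit Rrm2 (-2.78 ± 0.27), and 0 passed with 10. The 3 lists were lower with camera in the 9-array fit, with adjusted p of 0.00146, 2.59e-10 and 1.21e-07, and lost the call with adjusted p = 0.141, 0.352 and 0.352 with an estimated correlation. The 3 globins of the erythroid list that are embryonic, Hba-x, Hbb-bh1 and Hbb-y, fell in the 9-array fit (Hbb-y by 4.01 ± 0.28). Alas2, the heme synthesis enzyme of red cells, rose by 0.83 ± 0.20 (named after its values were seen). The list of 13 genes had 3 higher and 4 lower (camera adjusted p = 0.239).

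Of 25 pregranulosa and ovarian somatic genes 3 rose and 1 fell with 10 arrays, and 12 rose and 6 fell with 9. Irx3 and Lgr5, markers of ovarian supporting cells, rose by 3.27 ± 0.43 and 3.17 ± 0.39 in the 10-array fit, and Sprr2d fell by 3.20 ± 0.45. Krt19, a keratin of surface epithelium, rose by 4.06 ± 0.42 and Dmrt1 fell by 1.89 ± 0.33, the 2 of 19 genes of the early gonad and coelomic epithelium that passed with 10 arrays. With 9 arrays 3 of the 19 rose and 10 fell, Emx2 (-2.50 ± 0.22) and Tcf21 (-2.33 ± 0.26) among them. Of 19 endothelial genes 8 fell and 0 rose with 9 arrays, Plvap by 2.42 ± 0.30, and with 10 arrays 1 fell, Emcn, by 2.02 ± 0.38. In the 9-array fit camera gave adjusted p of 0.0323 (higher), 0.0265 (lower) and 0.00313 (lower) for these lists, and none passed with adjusted p = 0.450, 0.371 and 0.352 with an estimated correlation.

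Genes known from other organs were also among the largest changes. Alb, the serum albumin made by liver, rose in the 10-array fit, from 50.9 ± 2.56 to 2127 ± 187 (adjusted p = 0.0119), and Ttr, a carrier protein of plasma, rose by 4.25 ± 0.69. Cpa1 and Pnliprp2, digestive enzymes of the exocrine pancreas, fell by 4.92 ± 0.80 and 4.61 ± 0.61, from 658 ± 197 and 573 ± 129 to 5.91 ± 4.30 and 8.47 ± 7.47. Bzw2 rose by 7.74 ± 0.88, from 50.9 ± 1.02 to 14302 ± 1077, on its brightest probe set. The other tested probe set of Bzw2 was lower at E18.5 by the 9-array test (-0.94 ± 0.29, adjusted p = 0.0303).

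In all, 302 of 28857 probe sets differed between E18.5 and E11.5 with 10 arrays, 203 higher and 99 lower, by brightest probe set 132 genes higher and 62 lower. With 9 arrays 7214 of 27510 differed, 3233 higher and 3981 lower (1765 and 2176 genes), and all 302 were among them. Their direction was the same by construction, since both fits give a probe set the same change here. The higher share of the 7214 was 44.8%, and 56.7% of the calls on values as deposited, where the median change of all probe sets was 0.15 against 0.03 with the scaling used. The 302 became 15 and 4 without E11.5 replicates 1 and 2, 7183 and 7214 without E12.5 replicates 1 and 2, 133 and 122 without E14.5 replicates 1 and 2, 139 and 140 without E16.5 replicates 1 and 2, and 11 and 10 without E18.5 replicates 1 and 2. The 7214 fell to 3737 without E18.5 replicate 1 and to 4314 without E18.5 replicate 2, and were 7218 without both E12.5 arrays.

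**Figure D2:**
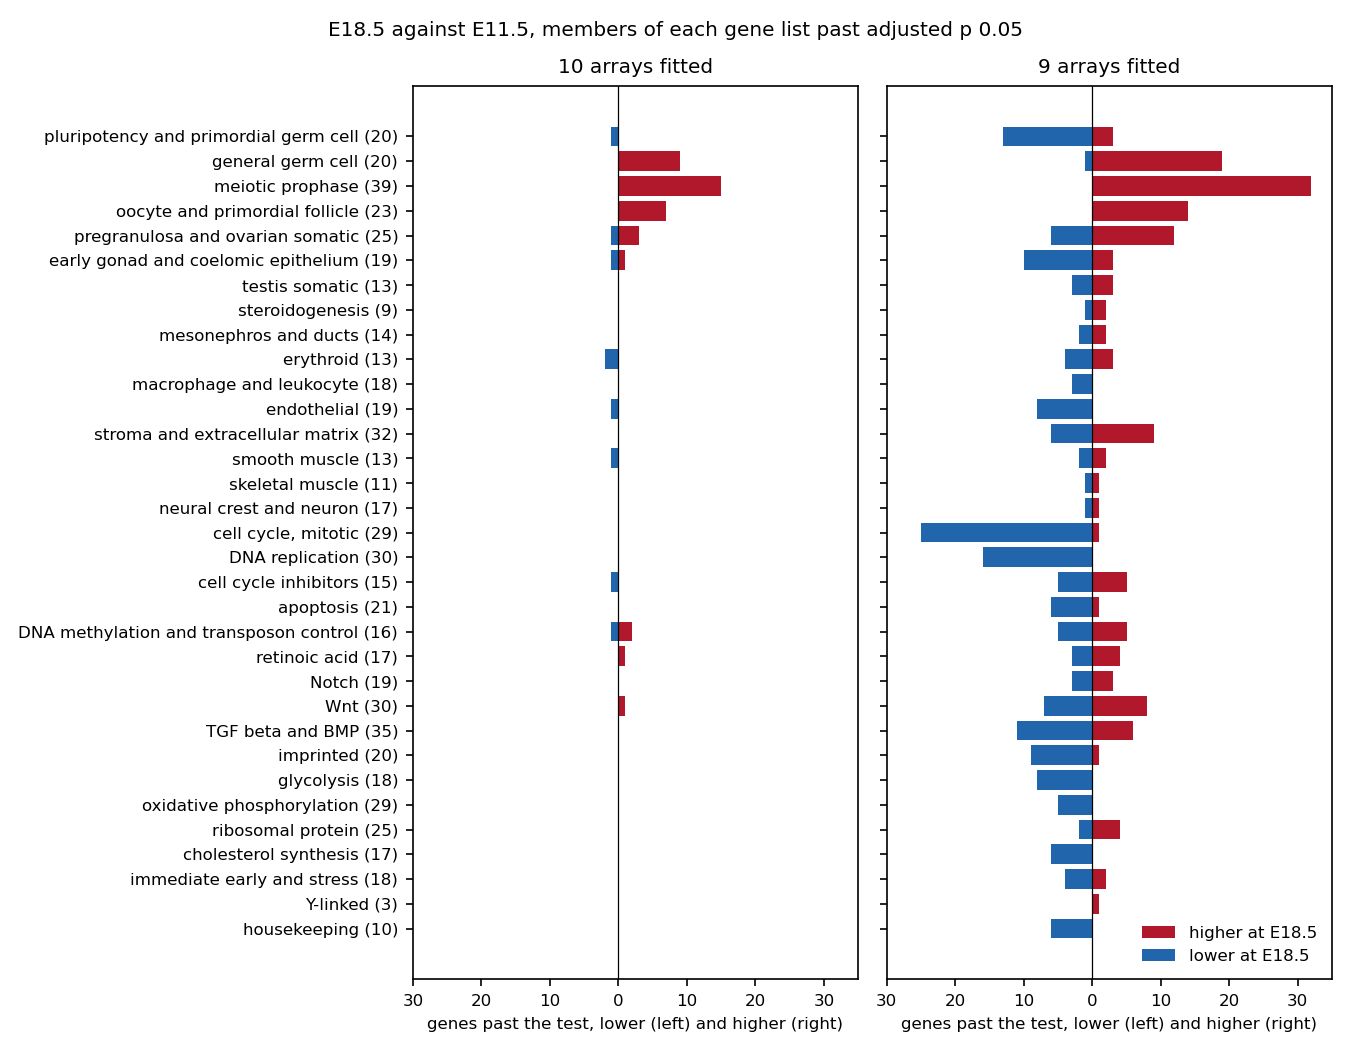
Bars give the number of genes of each fixed list, with its number of measured genes in the 9-array fit in parentheses, that were higher (red, right) or lower (blue, left) at E18.5 than at E11.5 at an adjusted p under 0.05, in the fit of 10 arrays and of 9 arrays. Meiotic prophase has the most higher genes, 15 and 32, and the mitotic cell cycle the most lower genes with 9 arrays, 25.

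Across all 5 stages 424 of 28857 probe sets (182 genes) changed by the limma F test with 10 arrays, and 9267 of 27510 (4721 genes) with 9, the 424 among them. Stra8, which starts meiosis in response to retinoic acid, and Rec8, a meiotic cohesin, were highest at E14.5, at 1404 ± 284 and 223, against 261 ± 7.57 and 43.0 ± 5.01 at E16.5. Dmc1, the recombinase of meiotic strand exchange, was highest at E16.5, at 515, against 276 ± 37.6 at E14.5 and 132 ± 15.7 at E18.5. Lhx8, Nobox, Nlrp4f and Nlrp5 of the oocyte were highest at E18.5, with the gap to the next stage between 3.22 (Nlrp5) and 4.03 (Lhx8) on the log2 scale. Tfap2c, a factor of primordial germ cells, was highest at E12.5, with 460 on replicate 1, against 135 ± 27.8 at E11.5 and 10.6 ± 1.67 at E16.5. H2-D1, a class I histocompatibility gene, was highest at E16.5, at 974 ± 219, and Gk5 at E11.5, at 508 ± 51.4.

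Of the 182 genes of the 10-array fit 75 were highest at E18.5, 36 at E16.5, 21 at E14.5, 28 at E12.5 and 22 at E11.5. Of the 4721 genes with 9 arrays 1777, or 37.6%, were highest at E12.5, where the single array had the Actb ratio of 10.6, while 1131 were highest at E18.5 and 966 at E11.5. Without both E12.5 arrays 6710 probe sets changed. The 424 became 22 and 26 without E11.5 replicates 1 and 2, 19357 and 9267 without E12.5 replicates 1 and 2, 68 and 74 without E14.5 replicates 1 and 2, 79 and 75 without E16.5 replicates 1 and 2, and 50 and 28 without E18.5 replicates 1 and 2.

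**Figure D3:**
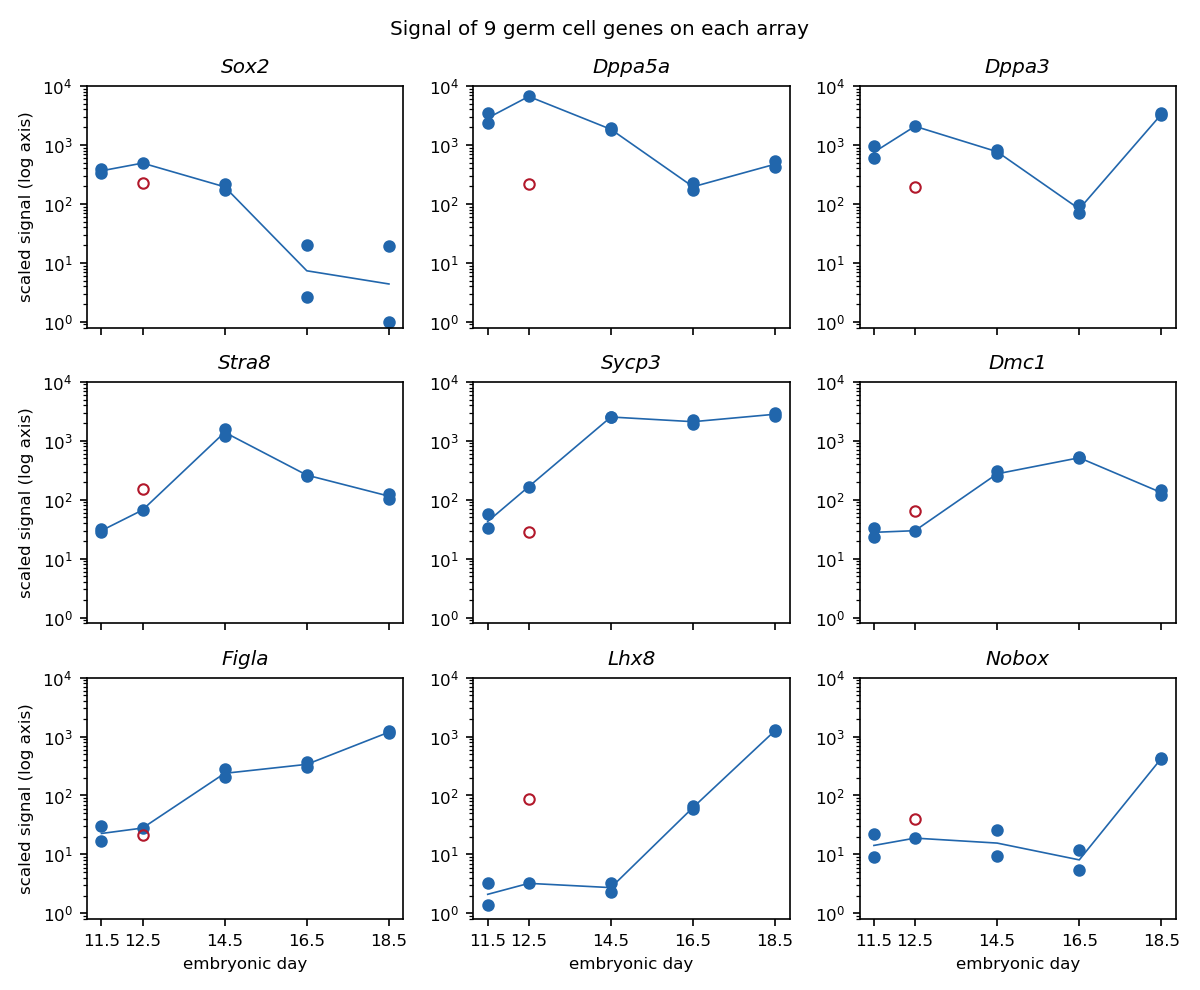
Points are the scaled signals (log axis, values under 1 drawn at 1) of 9 germ cell genes on each array by embryonic day, the line joins the geometric means per stage, and the hollow red point is E12.5 replicate 2, left out of the line. Stra8 peaks at 1404 at E14.5, Dmc1 at 515 at E16.5, and Lhx8 reaches 1268 at E18.5.

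Between E11.5 and E12.5, 3 genes rose and 11 fell in the 10-array fit by brightest probe set. Afp, the fetal serum protein of liver and yolk sac, rose by 2.92 ± 0.48, with 8.15 and 12.3 at E11.5 and 210 and 156 at E12.5. Snhg3, a host gene of small nucleolar RNA, rose by 2.85 ± 0.41, and Mmp23, a matrix metalloproteinase, by 2.04 ± 0.36. Rrm1, the large subunit of ribonucleotide reductase, fell by 2.48 ± 0.44, Tom1l1 by 2.51 ± 0.35 and Usp8, a ubiquitin protease, by 2.41 ± 0.40. Afp, Rrm1, Tom1l1 and Usp8 read under 203 on E12.5 replicate 2. In the 9-array fit another probe set of Rrm1 was the brightest, and it did not pass (adjusted p = 0.951). With E12.5 replicate 1 alone, Dazl, an RNA-binding protein that licenses germ cells for meiosis, rose by 2.07 ± 0.32 and Ddx4, a germ cell helicase, by 1.26 ± 0.24. Among ovarian somatic genes of the 9-array fit Bmp2 and Irx3 rose by 2.06 ± 0.25 and 1.84 ± 0.25, and the endothelial genes Pecam1 and Emcn fell by 2.86 ± 0.37 and 1.87 ± 0.32.

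In groups, 8 of 20 general germ cell genes, 11 of 39 meiotic genes (Smc1b 1.83 ± 0.28, Rec8 1.74 ± 0.38) and 5 of 25 pregranulosa genes rose with 9 arrays, with 0 lower in each, and 0 of any of the 3 lists passed with 10. Camera gave these lists adjusted p of 8.03e-04, 2.99e-05 and 0.0299 with 9 arrays, and adjusted p = 0.408, 0.416 and 0.640 with an estimated correlation. Of 25 ribosomal protein genes 3 rose and of 29 oxidative phosphorylation genes 8 rose (camera adjusted p = 5.81e-07 and 9.56e-04, and adjusted p = 0.656 for both with an estimated correlation). These counts and those of the 3 lists before are with 9 arrays, where E12.5 is replicate 1 alone, with its Actb ratio of 10.6. The lists were counted on brightest probe sets, of which more were higher than lower among all genes. With 10 arrays 0 genes of the ribosomal protein or oxidative phosphorylation list passed. Both of these lists had the opposite direction there, with medians of -0.81 and -1.24 (camera adjusted p = 0.684 and 0.0654). The direction of the ribosomal protein list also turned with quantile normalization of the 9 arrays (adjusted p = 0.994).

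In this interval 188 of 28857 probe sets differed with 10 arrays, 13 higher and 175 lower, and 2486 of 27510 with 9, 1027 higher and 1459 lower, with 187 of the 188 among them. The higher share of the 2486 was 41.3%, 31.1% on values as deposited and 26.1% after quantile normalization, and the median change of all probe sets was 0.12, 0.00 and 0.05. By brightest probe set the majority of the 9-array calls was higher instead, so the majority direction depended on which probe sets were counted. Both stages lay in 1 wash run, and a limma fit of their 4 arrays alone called 0 probe sets. The 188 became 0 without any 1 of the 8 arrays of E11.5, E14.5, E16.5 or E18.5, 17921 without E12.5 replicate 1 and 2486 without E12.5 replicate 2, and the 2486 became 1401 without E11.5 replicate 2.

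From E12.5 to E14.5 Tex101, a germ cell membrane protein, rose by 5.03 ± 0.33 in the 10-array fit, from 8.20 ± 2.63 to 778 ± 119 (adjusted p = 0.00186). Tex12 and Sycp3 of the synaptonemal complex rose by 4.85 ± 0.51 and 4.82 ± 0.65, Terb1 by 4.43 ± 0.47 and Smc1b by 4.27 ± 0.59. Stra8 rose by 3.58 ± 0.41 and Figla by 2.65 ± 0.35. Aplnr, the apelin receptor, fell by 3.33 ± 0.56, Sprr2d by 3.31 ± 0.45, Snhg3 by 2.48 ± 0.41 and Tfap2c by 2.32 ± 0.32, the 4 genes that fell with 10 arrays.

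Of 39 meiotic genes 14 rose and 0 fell with 10 arrays, and 28 rose and 2 fell with 9 (camera adjusted p = 2.01e-19 and 4.96e-31, and adjusted p = 0.0121 and 0.0381 with an estimated correlation). Of 20 general germ cell genes 4 rose and 0 fell with 10 arrays and 9 rose and 0 fell with 9, with camera adjusted p of 2.77e-06 and 3.59e-13, and adjusted p = 0.148 and 0.0372 with an estimated correlation. Of 20 genes of pluripotency and primordial germ cells 7 fell and 0 rose with 9 arrays, Dppa5a by 1.84 ± 0.28 and Dppa4 by 1.56 ± 0.32 (camera adjusted p = 1.73e-05, and adjusted p = 0.0698 with an estimated correlation). These falls start from E12.5 replicate 1 alone, where Dppa5a read 6647, against 2910 ± 752 at E11.5 and 1843 ± 111 at E14.5. Hbb-bh1 and Hba-x fell by 4.86 ± 0.30 and 3.50 ± 0.25 with 9 arrays. Of 29 oxidative phosphorylation genes 6 fell and of 25 ribosomal protein genes 2 fell with 9 arrays (camera adjusted p = 0.00803 and 4.54e-05, and adjusted p = 0.873 for both with an estimated correlation). With 10 arrays 0 genes of either list passed and both had the opposite direction (camera adjusted p = 0.0653 and 0.509). Both directions also turned with quantile normalization of the 9 arrays, with adjusted p = 0.0540 and 0.767.

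The counts were 154 of 28857 probe sets with 10 arrays, 149 higher and 5 lower, and 3065 of 27510 with 9, 1559 higher and 1506 lower, with all 154 among them. The higher share of the 9-array calls was 50.9%, 69.8% on values as deposited and 74.1% after quantile normalization, with a median change of all probe sets of -0.09, 0.10 and -0.05. By brightest probe set most of the called genes were lower with the scaling used, unlike the near even split of probe sets. The stages lay in different wash runs. The 154 became 2 and 4 without E11.5 replicates 1 and 2, 0 and 1 without E14.5 replicates 1 and 2, 6 without any 1 of the arrays of E16.5 or E18.5, 17264 without E12.5 replicate 1 and 3065 without E12.5 replicate 2, and the 3065 became 1397 and 1911 without E14.5 replicates 1 and 2.

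A comparison of E14.5 with E11.5, added after the data were seen, needed no E12.5 array. Terb1, Tex12, Sycp3 and Smc1b rose by 5.51 ± 0.47, 5.46 ± 0.51, 5.43 ± 0.65 and 5.19 ± 0.59 in the 10-array fit, Tex101 by 5.20 ± 0.33 and Stra8 by 4.94 ± 0.41. Of 39 meiotic genes 18 rose with 10 arrays and 30 with 9, and 0 fell in either fit, and the list passed with adjusted p = 6.81e-04 and 0.0160 with an estimated correlation. Afp rose by 5.77 ± 0.48, its replicates at E14.5 reading 866 and 2295, and of 11 skeletal muscle genes 4 rose with 9 arrays, among them Acta1 (2.61 ± 0.45) and Myh3 (1.72 ± 0.39), with adjusted p = 0.0993 for the list with an estimated correlation. Rgs5, a gene of vessel pericytes, fell by 2.61 ± 0.34.

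This comparison gave 74 probe sets with 10 arrays, 65 higher and 9 lower, and 1271 with 9, 752 higher and 519 lower, with a higher share of 59.2%, or 69.5% on values as deposited. The 74 became 0 without either E11.5 array, 1255 and 1271 without E12.5 replicates 1 and 2, 3 and 1 without E14.5 replicates 1 and 2, 30 without either E16.5 array and 32 without either E18.5 array, and the 1271 became 820 without E11.5 replicate 1 and 484 without E14.5 replicate 1.

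Between E14.5 and E16.5 no gene passed in the 10-array fit, and the changes named here are those of the 9-array fit. Dppa5a fell by 3.14 ± 0.23, from 1843 ± 111 to 197 ± 38.0, Sox2 by 3.02 ± 0.37 and Lin28a, a repressor of let-7, by 2.38 ± 0.38. Dppa3 went from 769 ± 72.0 to 83.1 over the same interval. Hbb-y, an embryonic globin, fell by 4.06 ± 0.28, Phlda2, an imprinted gene, by 3.72 ± 0.42 and Rhox5, a homeobox gene, by 3.17 ± 0.24. Stra8 and Rec8 fell by 2.34 ± 0.22 and 2.02 ± 0.31, while Syce3 rose by 1.86 ± 0.26. Lhx8 rose by 2.07 ± 0.30, Foxl2, the ovarian factor of granulosa cells, by 1.17 ± 0.20, from 237 ± 26.9 to 550 ± 12.1, and Bzw2, on its brightest probe set, by 4.68 ± 0.20, while its other probe set did not pass (-0.25 ± 0.29). Mfap4, a protein of extracellular microfibrils, rose by 2.81 ± 0.57, with 460 and 140 on the arrays of E16.5.

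Of 20 genes of pluripotency and primordial germ cells 9 fell and 0 rose (camera adjusted p = 9.39e-11, and adjusted p = 0.0553 with an estimated correlation). Of 29 mitotic genes 9 fell, Cdc20 by 1.65 ± 0.31, and of 30 DNA replication genes 6 fell, Tk1 by 1.48 ± 0.23, with 0 higher in both (camera adjusted p = 9.11e-11 and 7.52e-07, and adjusted p = 0.429 for both with an estimated correlation). Of 17 cholesterol synthesis genes 3 fell, Fdps by 1.41 ± 0.20, and of 11 skeletal muscle genes 3 fell, Myh3 by 1.77 ± 0.39, with camera adjusted p of 0.0311 and 0.00488, and adjusted p = 0.404 and 0.277 with an estimated correlation. Of 32 genes of stroma and extracellular matrix 2 rose, Mfap4 and Sparc (0.88 ± 0.20), with a camera adjusted p of 2.37e-05, a call that was lost with an estimated correlation.

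With 10 arrays limma called 0 of 28857 probe sets, and 988 had an unadjusted p under 0.05, while with 9 arrays 841 of 27510 differed, 302 higher and 539 lower. Both stages lay in 1 wash run, and a fit of their 4 arrays alone called 467 probe sets. The 0 became 856 and 841 without E12.5 replicates 1 and 2. The 841 became 1458 and 1468 without E11.5 replicates 1 and 2, 203 and 63 without E14.5 replicates 1 and 2, 34 without E16.5 replicate 2, and 350 without either E18.5 array.

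From E16.5 to E18.5 Nobox, Nlrp5 and Sohlh1 rose by 4.18 ± 0.44, 3.28 ± 0.32 and 3.04 ± 0.31 in the 10-array fit, with an adjusted p of 0.0409 each, and were the only 3 genes that passed there. None of the 3 passed with a pseudocount of 1, no filter, the stricter filter, quantile normalization, values as deposited, the replicate block or no trend. Nobox and Sohlh1, transcription factors needed for primordial follicles, reached 428 ± 15.2 and 941 ± 4.95. Nobox, at 8.67 ± 4.46, lay under the 95th percentile of the unspiked controls on both E16.5 arrays, and its change was 5.55 with 1 added and 2.76 with 64. With 9 arrays Lhx8 and Nlrp4f also rose, by 4.03 ± 0.30 and 4.29 ± 0.42, and Dppa3, a maternal gene of the oocyte that protects methylation marks, rose by 5.09 ± 0.23, from 83.1 to 3320 ± 137. Ccno, an atypical cyclin, and Esrp1, a splicing regulator, rose by 3.68 ± 0.40 and 3.76 ± 0.39, and Kit, the receptor for stem cell factor, by 2.47 ± 0.25. Dmc1 and M1ap of meiosis fell by 1.84 ± 0.23 and 1.85 ± 0.24, and Mfap4 by 2.96 ± 0.57.

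Of the oocyte and primordial follicle genes 3 of 24 rose with 10 arrays and 10 of 23 with 9, and 0 fell in either fit (camera adjusted p = 4.16e-29 and 3.17e-20, and adjusted p = 0.00172 and 0.0148 with an estimated correlation). Of 20 general germ cell genes 5 rose with 9 arrays, Tdrd9 by 2.84 ± 0.37 and Piwil2 of the piRNA pathway by 2.02 ± 0.22, and of 20 genes of pluripotency and primordial germ cells 5 rose, with 0 lower in both (camera adjusted p = 1.94e-06 and 5.74e-06, and adjusted p = 0.0595 for both with an estimated correlation). The latter list holds Dppa3 and Kit, given above, and Kit is also in the oocyte list, so this is not a separate rise of pluripotency genes. Of 39 meiotic genes 6 fell and 1 rose with 9 arrays, Psma8 by 1.62 ± 0.25 (camera adjusted p = 0.0323, and adjusted p = 0.468 with an estimated correlation), and of 32 genes of stroma and extracellular matrix 3 fell (adjusted p = 0.447 with an estimated correlation). The liver gene Ttr rose by 2.16 ± 0.36 in the same fit.

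The 3 probe sets were all that differed of 28857 with 10 arrays, where 809 had an unadjusted p under 0.05, and 221 of 27510 differed with 9, 167 higher and 54 lower. The stages lay in different wash runs. The 3 became 0 without any 1 of the 8 arrays of E11.5, E14.5, E16.5 or E18.5, and 231 and 221 without E12.5 replicates 1 and 2. The 221 became 49 without E16.5 replicate 1, and 30 and 60 without E18.5 replicates 1 and 2.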

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

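The 9-array fit, array quality weights, the fits without both E12.5 arrays, the comparison of E14.5 with E11.5 and every alternative of the 9-array fit were chosen after the data were seen, and the other alternatives before. In the 10-array fit the replicate block left 206 probe sets changed over the 5 stages, 43 for E12.5 against E11.5, 61 for E14.5 against E12.5 and 0 for E18.5 against E16.5. Only the numbers of the replicates are shared between stages, and the differences between replicates 1 and 2 correlated at -0.073 to 0.036 over the 6 pairs of stages with sound arrays. A scan date block was not run, since the date does not cross the stages. In the same order, no filter gave 220, 42, 65 and 0, a pseudocount of 1 gave 280 over the 5 stages and 0 for E18.5 against E16.5, and a pseudocount of 64 gave 23 for the latter. Quantile normalization gave 51, 80, 2 and 0 for the 4 intervals in turn. The test without a trend gave 112 and 77 for the first 2 intervals, and it, the stricter filter and values as deposited each gave 0 for the last. Array weights gave 5858 over the 5 stages, 0, 0, 646 and 277 for the intervals, 7640 for E18.5 against E11.5, 1401 for E14.5 against E11.5 and 27 of the 46 named genes still past the test. Without both E12.5 arrays the counts were 6710, 864 (E16.5 against E14.5), 236 (E18.5 against E16.5), 7218 (E18.5 against E11.5) and 1287 (E14.5 against E11.5). Fits of the stages of a contrast alone gave 0, 0, 467 and 322 for the intervals, 6832 for E18.5 against E11.5 and 803 for E14.5 against E11.5. With an estimated correlation 5 of the 37 list calls held. The 37 list calls otherwise, and the counts for E18.5 against E11.5 and E14.5 against E11.5 under the alternatives not listed, stayed within 1.5 times.

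With 9 arrays the replicate block kept every count within 1.5 times (8491 over the 5 stages, 6976 for E18.5 against E11.5) and 72 of 72 named genes. No filter gave 1637 for E12.5 against E11.5, 295 for E16.5 against E14.5, 144 for E18.5 against E16.5 and 831 for E14.5 against E11.5. Quantile normalization gave 1595 and 1806 for the first 2 intervals. The test without a trend gave 1420, 1681 and 97 for the first 3 and 846 for E14.5 against E11.5. Fits of the stages alone gave 486 for E16.5 against E14.5 and 821 for E14.5 against E11.5, and requiring a 2-fold change left 4514 for E18.5 against E11.5. With an estimated correlation 6 of 47 list calls held. Quantile normalization turned the ribosomal protein list at E12.5 against E11.5 (adjusted p = 0.994) and at E14.5 against E12.5 (0.767) and the oxidative phosphorylation list at E14.5 against E12.5 (0.054), and the mean of all its probe sets turned Hmgcs1 at E12.5 against E11.5 to -0.28. The cause was not tested.

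Leaving out 1 array at a time gave these ranges. With 10 arrays the counts were 22 to 19357 over the 5 stages, 0 to 17921 for E12.5 against E11.5, 0 to 17264 for E14.5 against E12.5, 0 to 856 for E16.5 against E14.5, 0 to 231 for E18.5 against E16.5, 4 to 7214 for E18.5 against E11.5, 0 to 1271 for E14.5 against E11.5, 29 to 48 list calls and 4 to 46 named genes. With 9 arrays they were 6346 to 8491, 1401 to 3143, 1397 to 3774, 34 to 1468, 30 to 285, 3737 to 7265, 484 to 1287, 39 to 52 and 64 to 71, in the same order. The highest counts of the 10-array fit came without one or the other E12.5 array, the lowest without an array of another stage, and in the 9-array fit the lowest for E16.5 against E14.5 was without E16.5 replicate 2 and for E18.5 against E16.5 without E18.5 replicate 1. Signal over background limits the dim genes: control probe sets with no spiked target reached a 95th percentile of 18.7 to 33.5 on the other 9 arrays and 203 on E12.5 replicate 2.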

Other observations

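The tests of little RNA on E12.5 replicate 2 and of a swap of that array, and the marker lists, were chosen after the result was seen. From E11.5 to E18.5 in the 9-array fit, of 20 imprinted genes 9 fell and 1 rose, with Nnat at -1.92 ± 0.33, Mest at -1.47 ± 0.20 and Grb10, a growth factor receptor adapter, at -1.47 ± 0.20, and of 18 glycolysis genes 8 fell and 0 rose, with the glucose transporter Slc2a3 at -2.04 ± 0.30 and Ldhb at -1.53 ± 0.20 (camera adjusted p = 0.00353 and 0.00146, and adjusted p = 0.352 for both with an estimated correlation). Of 17 cholesterol synthesis genes 6 fell and 0 rose, with Sqle at -1.66 ± 0.21 and Msmo1 at -1.68 ± 0.21. Of 35 genes of TGF beta and BMP signalling 6 rose and 11 fell, the transcriptional inhibitor Id1 rising by 2.44 ± 0.18 and the ligand Bmp5 falling by 2.00 ± 0.36, and of 30 Wnt genes 8 rose and 7 fell, with the Wnt targets Axin2 and Apcdd1 higher by 1.47 ± 0.24 and 2.08 ± 0.22. Of 19 Notch genes 3 rose and 3 fell, the ligand Jag2 rising by 2.51 ± 0.24 and the effector Hes1 by 1.62 ± 0.20. Of 17 retinoic acid genes 4 rose and 3 fell, with the binding protein Crabp2 at -2.19 ± 0.26. Of 16 genes of DNA methylation and transposon control 5 rose and 5 fell, with Piwil2 at 3.13 ± 0.22 and L1td1 at -2.46 ± 0.34, and the list's median of -0.03 and mean of 0.39 differed in sign, as did those of the Wnt list, -0.12 and 0.06. Camera did not call the lists other than imprinted and glycolysis in this paragraph.

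Over the same span, of 32 genes of stroma and extracellular matrix 9 rose and 6 fell, with the collagens Col6a2 and Col1a1 higher by 2.20 ± 0.18 and 1.66 ± 0.22. Of 18 macrophage and leukocyte genes 3 fell and 0 rose, Csf1r, the receptor for a macrophage growth factor, by 1.17 ± 0.26. Of 13 testis somatic genes 3 rose and 3 fell, with Etv5 at -2.63 ± 0.27, of 9 steroidogenesis genes 2 rose and 1 fell, the corticotropin receptor Mc2r by 1.87 ± 0.44, and of 14 genes of mesonephros and ducts 2 rose and 2 fell. Of 13 smooth muscle genes 2 rose and 2 fell, of 11 skeletal muscle genes 1 rose and 1 fell, of 17 neural crest and neuron genes 1 rose and 1 fell, and of 3 Y-linked genes 1 rose, Zfy2 by 1.55 ± 0.42. Of 15 cell cycle inhibitors 5 rose, Cdkn1b by 1.31 ± 0.22 among them, and 5 fell, of 21 apoptosis genes 1 rose, Trp63, the oocyte guardian p63, by 1.79 ± 0.33, and 6 fell, and of 18 immediate early and stress genes 2 rose and 4 fell. Of 29 oxidative phosphorylation genes 5 fell and 0 rose, of 25 ribosomal protein genes 4 rose and 2 fell, and of 10 housekeeping genes 6 fell and 0 rose, with Pgk1 at -1.14 ± 0.25 and Tbp at -0.97 ± 0.20. Camera called none of the lists in this paragraph.

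E12.5 replicate 2 stood apart from the other 9 arrays. A swap with another array of the series would, by the limit set for it, need a correlation of at least 0.873, which any 2 of the others reached. Its highest was 0.470. An array with weak sample signal would correlate poorly with every stage, so this cannot decide which stage it came from. Another tissue or sample on a sound array is argued against by the ribosomal protein genes, whose median lay -2.71 from the other arrays on the log2 scale, when the lowest of the others was -0.468. Little sample RNA on the array, scaled up to the common mean, also stays open, and goes with spiked controls at 15.97 times the median of the other 9 arrays. Scaling alone leaves the embryonic globins unexplained. Hbb-y read 201683 on this array against 24166 on replicate 1, while Hba-x read 399 against 9144 and Hbb-bh1 463 against 9845. No biological explanation was tested for this array.

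In the 9-array fit 1474 probe sets went out at E12.5 and back by E14.5, 536 higher and 938 lower. Shortened labelled RNA on E12.5 replicate 1 could give such a pattern, and other probe sets of the same gene shared the direction in 61.0% of 2872 pairs against 75.7% of 9609 pairs for E18.5 against E11.5, a gap just under the 15 points set for it. The deviations of the brightest and next brightest probe set correlated across genes at 0.196, barely below the 0.202 of the lowest of the E14.5 and E16.5 arrays, and a margin for its error, added after that value was seen, left this open. Brightest minus next brightest had a median of 0.208 and an SD of 0.839 on E12.5 replicate 1. On the E14.5 and E16.5 arrays the medians were -0.044 to 0.055 and the SDs 0.438 to 0.534. By brightest probe set, more of the out and back genes were higher than lower, the reverse of all probe sets. These values go with shortened RNA, but they rest on 1 array and had no limit set in advance. A transient change of the E12.5 ovary also stays open. E12.5 replicate 2 had the same direction in 65.9% of the probe sets, 31.5% of the higher and 85.5% of the lower ones. Of all its probe sets 60.6% were lower, so agreement of the lower ones cannot decide this, and most of the higher ones disagreed. Its 3′ to 5′ ratios, 4.09 for Actb and 2.39 for Gapdh, were also above those of the other stages. A skew shared by both E12.5 arrays could thus give agreement too. The 2 explanations cannot be told apart here, since the other array of the stage is the one that stood apart.

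Genes of liver and pancreas were among the largest changes, and the levels of Alb, Afp, Cpa1 and Pnliprp2, with those of some other members, had been seen before the lists were tested. Hepatocyte RNA in the later preparations may account for the liver genes: without Afp and Alb the 18 tested genes of the hepatocyte list had a median change of 1.99 from E11.5 to E18.5, with 11 higher and 0 lower, among them Ttr, Apoa1, Ahsg and Fgb at 364, 245, 240 and 140 on E18.5 replicate 2, where Alb read 2259. The filter bears on these counts, since a gene such as Fgb, at 2.5 and 3.9 at E11.5, passed it only through its E18.5 values. Dim members left untested went both ways. Apob read 25.5 and 27.6 at E11.5 and 10.7 and 25.3 at E18.5, and Itih3 1.1 and 7.5, then 44.9 and 44.8. The median and counts thus hold for the tested genes and not for the whole list. Expression of the liver genes by cells of the ovary itself stays open and untested, and the retinoic acid list also holds Ttr and Rbp4. By the limits set for its list, exocrine pancreas RNA at E11.5 was not borne out, but the list cannot decide it, for the reason given below. Without Cpa1 and Pnliprp2 the 9 tested genes had a median change of 0.061, with 0 higher and 1 lower (Ctrl, -1.62 ± 0.41), so no shift was shared by the list. Several of them had little room to fall, such as Clps at 36.1 and 51.0 and Cel at 45.6 and 37.6 on the E11.5 arrays. The unspiked controls had a 95th percentile of 18.7 to 33.5 on the arrays other than E12.5 replicate 2. Pnliprp1, at -1.53 ± 0.54 (limma adjusted p = 0.0519), lay in the same direction as Ctrl, Cpa1 and Pnliprp2. Afp read 866 and 2295 and Alb 243 and 583 on E14.5 replicates 1 and 2, so replicates of a stage differed in these genes.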
